A study of Arabidopsis thaliana with 6 samples.

How the data were processed

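Transcript levels were measured in whole rosettes of Arabidopsis thaliana aged 35 days with Affymetrix ATH1 arrays. Per the labels, 3 arrays held RNA of Col-0 wild type plants and 3 held RNA of plants in which the genes PVIP1 and PVIP2 were targeted by RNA interference (RNAi). Plants grew for 14 days on agar plates and then for 3 weeks on soil with 8 h of light a day. The plates of the RNAi line contained phosphinothricin, the herbicide that selects for its transgene, and those of the wild type are not described as containing it. The labels give the background of the RNAi line as Col-3 and that of the wild type as Col-0, and they call the line both an RNAi line and a double knockout. Any difference between the groups can therefore belong to the RNAi, to the background or to the selection. Growth, harvest or array handling that differed between the groups could not be told apart from these either. Nothing in the labels says whether the 3 samples of a group came from separate plants, pools or harvests, so p-values measure the spread between these samples, which may be technical.

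The deposited intensity values are linear MAS5 signals, made by the authors with Affymetrix GCOS, per the submitters' processing notes, which give no version. Per the labels' protocols, total RNA was labelled by the one-cycle method, which primes on poly(A) tails. In the deposited table the mean signal without the lowest and highest 2% of probe sets is 100 on every array, so the arrays were scaled to one another before deposit. MAS5 summarises perfect-match and mismatch probes into 1 value per probe set and leaves values above 0 for all of them, including probe sets whose transcript is absent. Detection calls were not used here, and neither were scanner images. The number of arrays limits the precision.

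Of 22810 probe sets, 64 control probe sets were left out of the limma and list tests and used to describe the arrays. The platform annotation used here names 1 gene for 13513 probe sets, several genes for 503 and none for 8730, which are unnamed here. Of the probe sets with 1 gene, 13436 were matched to the RefSeq gene table of assembly TAIR10.1, from which symbols were taken, and 77 kept the name of the platform annotation. No coordinates are given, since the build behind the array annotation is not given in the sources used here. No gene was named from a probe set with several genes.

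Signals were transformed as log2(signal + 6.54), the offset being the median over the 6 arrays of their 20th percentile of signal. Fold changes on this scale understate the change of dim genes. The 30% of probe sets with the lowest mean were dropped, which left 15922, and the values were not rescaled. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), as RNAi minus wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe set past it is said to have risen or fallen. Values per group are means ± SD of the MAS5 signal over 3 arrays, and errors of log2 fold changes are limma's standard errors (SE).

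Background was taken as the highest signal among 27 control probe sets for Bacillus subtilis genes on each array, a definition chosen after the data were seen. Where all 3 arrays of a group lay at or below it, the change is given as "at least N-fold", the brighter group's mean log2 signal against the mean of, per array, the higher of the background and the dim probe set's own signal. No offset enters that bound.

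A total of 31 gene lists with 579 entries was fixed before the data were examined, as were the tests, the rule for naming genes and most of the alternative settings. Named probe sets existed for 81 entries, and 4 entries were left out because the annotation gives their symbol to another locus. A member is called measured where it has a named probe set among those tested. Other members may be on the array without a name here, so the measured ones do not stand for the whole list. The 11 lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01 between genes, with the brightest probe set for each gene, and p-values were adjusted over these 11. Members are counted as adjusted over all probe sets and as adjusted over the list alone. A further 28 families, from symbol prefixes and from genes encoded in the plastid or the mitochondrion, were written down after the data had been opened and before any of them was tested. The matching of prefixes was made to ignore letter case after results for single genes had been seen. They were adjusted over the 28.

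The rule for naming genes took the PVIP/OBERON family genes, the 12 largest rises and the 12 largest falls among probe sets with 1 gene that passed the test without overlap between the groups, and from each list up to 4 members past the test by size, or the 2 with the smallest p given as values. Reference genes are summarised. Control probe sets and RNA quality ratios were compared with a two-sided exact permutation test, for which 3 arrays against 3 give 0.1 as the smallest p. The tests were tried on simulated data with the real probe sets' means and spread, in which 200 of the probe sets had been changed. Of those 200, 176 were among the 15922 tested, and limma recovered 52.2% of 2-fold and 92.9% of 4-fold changes with 0 false calls. With random lists, in data where no other gene was changed, camera called 10 of 10 lists whose members were all raised 2-fold and 0 of 10 others. In the real data 5584 probe sets changed, list members shifted unequally and some lists were smaller, so these rates need not hold there. The simulated noise was independent between probe sets, so this trial does not show how often camera calls lists of genes that vary together.

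The alternative settings chosen beforehand were other offsets and filters, quantile normalization, centring on the median, the replicate number as a block, leaving out each array in turn, other variance models and array weights, other sets of probe sets, a looser threshold, and other tests of the lists. Cyclic loess normalization, the families, the family without CYP71 and the comparisons with probe sets of like brightness were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.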

Results

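Gene expression was compared between whole rosettes of a PVIP1 and PVIP2 RNAi line (3 arrays) and of Col-0 wild type plants (3 arrays). PVIP proteins carry a PHD finger domain, bind the genome-linked protein of potyviruses and are also known as OBERON proteins, which act in meristem and root initiation in Arabidopsis. The question was which transcripts differ when these genes are targeted. After the authors' scaling the median signal was 35.7 to 38.3 on the wild type arrays and 37.7 to 40.7 on the RNAi arrays. The share of probe sets above the B. subtilis background was 66.2% to 69.5% in wild type and 75.4% to 78.7% in RNAi arrays. That background itself was higher in wild type, at 14.8 to 19.2, than in RNAi arrays, at 7.86 to 10.4. The shares thus do not compare numbers of expressed genes. The same dim signal can count as background in wild type and as above it in RNAi arrays. No pair of arrays held identical values.

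Of the targeted family, only OBE1 (AT3G07780) has a named probe set here, and its signal was lower in 2 of the 3 RNAi arrays. It read 23.1, 38.0 and 16.8 in the wild type arrays 1 to 3, against backgrounds of 19.2, 14.8 and 15.6. Wild type arrays 1 and 3 thus lay little above background. In the RNAi arrays 1 to 3 it read 19.9, 2.33 and 5.38, so that RNAi array 1 lay within the wild type range and the other 2 lay at or below background. The log2 fold change was −1.16 ± 0.45 (SE), with a limma adjusted p of 0.0625 over all probe sets, and thus not past the test. Adjusted over the list alone, where it is the single tested member, it passed. It also passed with the arrays centred on their medians (−1.22, limma adjusted p = 0.0445) and without RNAi array 1 (−1.61, adjusted p = 0.0213). OBE2, TTA1 and TTA2 are unnamed here and were not analysed, and the sources used here do not say which part of OBE1 the RNAi construct holds. The label of RNAi array 1 is thus not checked by this gene.

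**Figure D1:**
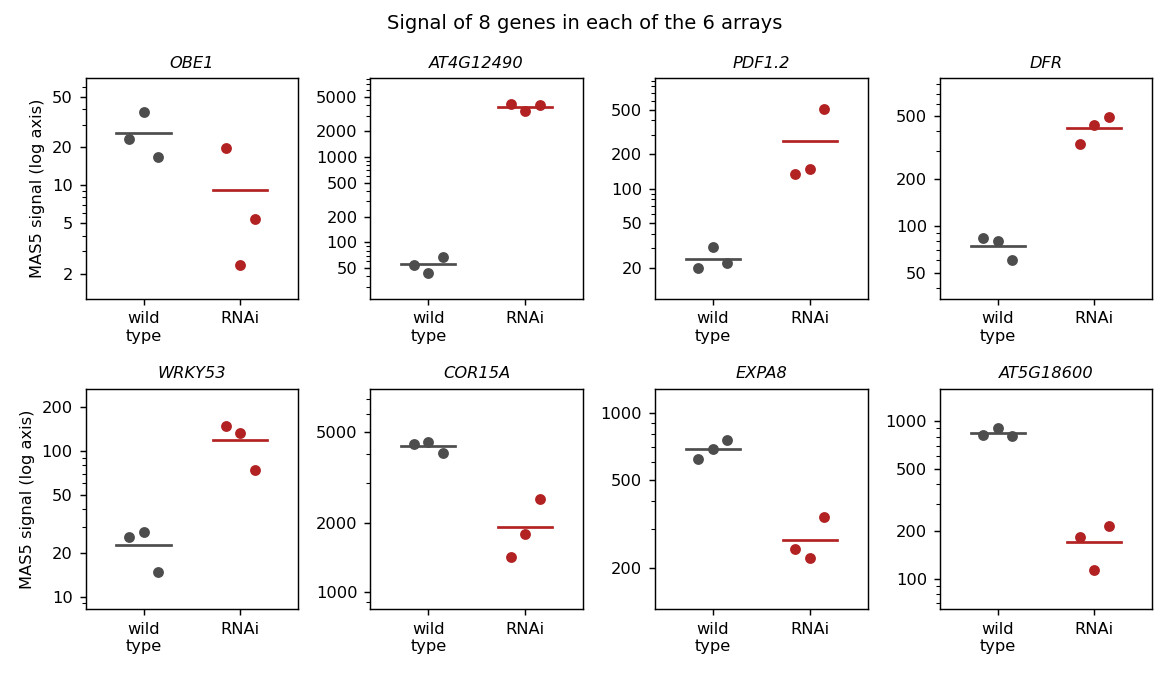
MAS5 signal of 8 genes (log axis, separate for each gene) in the 3 wild type arrays (grey) and the 3 RNAi arrays (red); points are arrays and lines are group means. OBE1 overlaps between the groups, at 16.8 to 38.0 against 2.33 to 19.9, while the other 7 genes do not.

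The arrays of the groups stood far apart. Arrays correlated at 0.959 to 0.964 within wild type (Pearson's r across probe sets, which are not independent), at 0.968 to 0.973 within RNAi and at 0.909 to 0.931 between the groups. The leading principal component held 69.3% of the variance and separated the groups. In limma, 5584 of 15922 probe sets changed (35.1%), of which 2953 rose and 2631 fell in the RNAi line. At the offset used, which compresses the changes of dim probe sets, 1276 probe sets rose and 503 fell more than 2-fold, and 112 rose and 0 fell more than 8-fold. With the offset at the 1st percentile 186 rose and 4 fell more than 8-fold. With it at the 40th percentile 45 rose and 0 fell more than 8-fold, and 847 rose and 289 fell more than 2-fold. At the offset used, 6998 probe sets had an unadjusted limma p under 0.05. The groups did not overlap for 5448 of the changed probe sets and for 7600 of all those tested, where chance gives 10%. Of the changed probe sets, 2819 name 1 gene, 2644 are unnamed here and 121 name several. Taking the brightest probe set for each of 8734 genes, 1386 genes rose and 1409 fell.

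The 12 largest rises included AT4G12500 and AT4G12490, neighbouring genes of the lipid transfer protein cluster that holds AZI1 and EARLI1, which rose by 6.47 ± 0.32 and 5.97 ± 0.14 (log2 ± SE). The signal of AT4G12490 went from 55.3 ± 11.4 to 3838 ± 392 (SD, n = 3 arrays each), with a limma adjusted p of 1.11e-10. Chitinase genes AT2G43620 and CHI (AT2G43570) rose by 5.27 ± 0.27 and 5.09 ± 0.36, and the peroxidase gene AT5G64120 by 5.47 ± 0.33. OSM34, an osmotin-like protein, was at least 21.1-fold higher in the RNAi line, since all 3 wild type arrays lay at background. On the same basis AT1G13470 was at least 15.2-fold, the receptor kinase gene AT1G51850 at least 11.2-fold and the berberine bridge enzyme-like gene AT1G30700 at least 9.60-fold higher. The remaining genes by this rule were AT3G18250 (5.86 ± 0.33), AT1G65500 (4.90 ± 0.16) and the plant defensin PDF1.2b (4.39 ± 0.38). Of the genes given with a log2 value here, AT4G12500, AT2G43620, AT5G64120 and CHI lay above background in 1 of 3 wild type arrays each, and AT3G18250 and PDF1.2b in 2 of 3.

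The 12 largest falls included 4 glutaredoxin genes of the plant-specific CC type, a class that moved both ways, with 8 fallen and 3 risen of 15 measured. AT4G15690 was at least 5.82-fold lower in the RNAi line, where all 3 arrays lay at background, and AT3G62950, AT5G18600 and AT4G15680 fell by 2.38 ± 0.33, 2.29 ± 0.19 and 1.90 ± 0.37 on the log2 scale. AT5G18600 was the brightest of them, at 839 ± 54.1 in wild type and 171 ± 53.1 in RNAi arrays. The methionine sulfoxide reductase gene MSRB6 (−2.48 ± 0.27), the dehydrin gene AT1G54410 (−1.96 ± 0.26) and CRR41 (−1.95 ± 0.26), which serves the assembly of the chloroplast NDH complex, fell too. The others were AT1G13650 (−2.26 ± 0.21), AT1G67865 (−2.11 ± 0.12), AT3G26960 (−2.03 ± 0.17), AT5G22430 (−2.02 ± 0.35) and AT1G51080 (−1.95 ± 0.34). AT3G62950, AT5G22430 and AT1G51080 lay above background in 1 of 3 RNAi arrays, and AT4G15680 in 2 of 3.

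Of 19 listed genes of flavonoid and anthocyanin synthesis 4 were measured. All 4 rose in the RNAi line, over all probe sets and adjusted over the list alone, with a median log2 fold change of 2.52. DFR, dihydroflavonol reductase, rose by 2.39 ± 0.17, from a signal of 74.4 ± 12.2 to 421 ± 82.4. The glycosyltransferase genes UF3GT and UGT78D2 rose by 2.64 ± 0.22 and 1.17 ± 0.17, and AT4G14090, an anthocyanin glucosyltransferase gene, was at least 12.2-fold higher. The list passed camera at an adjusted p of 2.81e-04; with an estimated correlation its adjusted p was 0.284. The 3 measured of 27 listed genes for salicylic acid and immunity rose as well, with a median of 1.52 (camera adjusted p = 0.0103, and 0.325 with an estimated correlation). They were WRKY53 (2.07 ± 0.26), GRX480, a glutaredoxin that binds TGA factors (1.52 ± 0.25), and SAG101, a lipase-like partner of EDS1 (0.92 ± 0.24). WRKY53 and GRX480 lay above background in 2 of 3 wild type arrays.

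Of 27 listed jasmonate and wounding genes 3 were measured. The defensins PDF1.2b and PDF1.2 rose, the latter by 2.89 ± 0.37, and THI2.1 read −0.41 ± 0.39, not past the test. The median was 2.89 and the list did not pass camera (adjusted p = 0.101; fry gave 0.0324). The probe set of PDF1.2b is of a kind that can also detect related transcripts. PDF1.2 varied among the RNAi arrays, at 262 ± 207 against 24.0 ± 5.40 in wild type (SD, n = 3 arrays each). STZ, a zinc finger gene and the single measured member of the touch and wound list, rose by 2.48 ± 0.20, and WRKY6, the single member measured for senescence, was at least 5.80-fold higher.

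**Figure D2:**
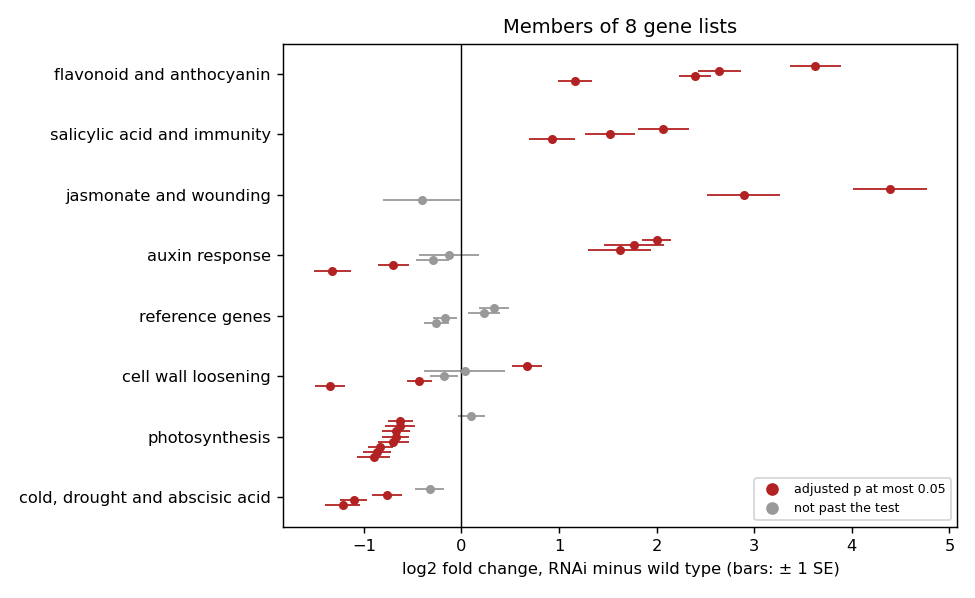
Log2 fold change (RNAi minus wild type, 3 arrays each) of the measured members of 8 gene lists, with bars of ± 1 SE; red points passed the limma test at an adjusted p of at most 0.05 and grey points did not. All 4 measured flavonoid and anthocyanin genes lie above 0, and 8 of 9 measured photosynthesis genes passed below it.

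Photosynthesis genes read lower in the RNAi line, as did other bright probe sets. Of 45 listed members 9 were measured. Of these 8 fell, over all probe sets and adjusted over the list alone, with a median of −0.67. PSAE-1 and PSAN of photosystem I fell by 0.90 ± 0.17 and 0.87 ± 0.14, the Calvin cycle enzyme gene PRK by 0.83 ± 0.13 and the antenna gene LHCB4.1 by 0.70 ± 0.16. The list passed camera (adjusted p = 0.00193), but not with an estimated correlation (adjusted p = 0.553) or after quantile normalization (adjusted p = 0.313, median −0.16). After that normalization LHCB4.1 was not past the limma test (−0.14, adjusted p = 0.333), nor was it without a filter (adjusted p = 0.0558). After cyclic loess LHCB4.1 (−0.048, limma adjusted p = 0.736) and PSAE-1 (−0.32, adjusted p = 0.0800) were both not past it. Among the brightest 2% of those tested, the 285 probe sets outside the photosynthesis list and the plastid-encoded genes had a median log2 fold change of −0.51. Of them 87.0% lay below 0. They may hold photosynthesis genes unnamed here, since only the 9 named members could be set apart. The 99th percentile of signal was 2480 to 2578 in the wild type and 1845 to 2092 in the RNAi arrays.

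Of 26 listed cold, drought and abscisic acid genes 4 were measured. Of these, the cold-regulated genes COR15A (−1.22 ± 0.18), COR15B and COR47 (−0.77 ± 0.15) fell. Adjusted over the list alone all 4 fell, and the median was −0.94. The signal of COR15A went from 4348 ± 256 to 1917 ± 570 and that of COR15B from 2407 ± 105 to 1126 ± 202. The list passed camera (adjusted p = 0.0188), but not with an estimated correlation (adjusted p = 0.284). Nor did it pass after quantile normalization (camera adjusted p = 0.104, median −0.68) or cyclic loess (0.129, median −0.62). These genes are bright too, and other probe sets of like brightness had a median of −0.33 (central 95% of 10000 random medians −0.81 to 0.24). The list lay below that range. The draws take each gene's match independently, while these 4 genes can vary together, so the range may be too narrow.

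**Figure D3:**
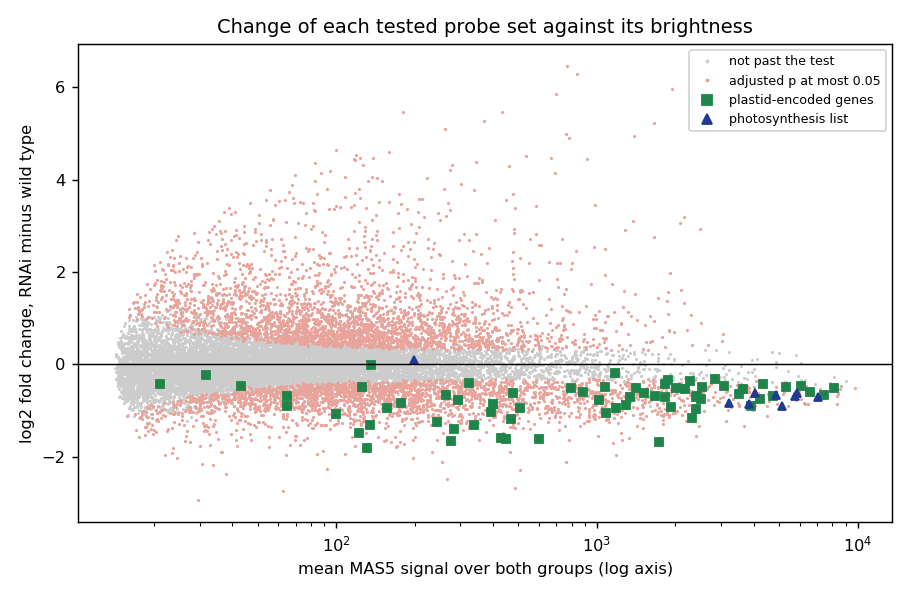
Log2 fold change of each of 15922 tested probe sets against its mean MAS5 signal (log axis), grey where not past the limma test and light red where past it, with plastid-encoded genes as green squares and the photosynthesis list as blue triangles. At the bright end most probe sets lie below 0. The brightest 2% without the marked genes have a median of −0.51, and photosynthesis genes unnamed here may be among them.

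Auxin response genes moved both ways. Of 7 measured, the auxin-conjugating enzyme genes WES1 (GH3.5) and GH3.3 rose, the former from a signal of 62.6 ± 10.9 to 268 ± 21.3 and the latter by 1.62 ± 0.32 on the log2 scale, and GH3.17 was at least 2.64-fold higher. GH3.3 lay above background in 1 of 3 wild type arrays. IAA29 fell by 1.32 ± 0.19 and HAT2 by 0.70 ± 0.16, and the other 2 were not past the test. The median was −0.13 while the mean was 0.42, and the list did not pass camera (adjusted p = 0.599). Of 5 cell wall loosening genes, the expansin genes EXPA8 and EXPA15 fell, by 1.35 ± 0.15 and 0.43 ± 0.13, and EXPA4 rose by 0.67 ± 0.15; the list did not pass (adjusted p = 0.548). EXPA15 was not past the limma test without wild type array 1 or 3 or RNAi array 1 (adjusted p = 0.0707, 0.0658 and 0.0632).

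Other lists had few measured members. GI, a clock gene, rose by 0.65 ± 0.12. AGO7 of the RNA silencing list rose by 1.18 ± 0.33, though not past the test without RNAi array 1 (limma adjusted p = 0.0571) and above background in only 1 of 3 wild type arrays, and SE read 0.27 ± 0.20. BCAT4 of glucosinolate synthesis fell by 0.82 ± 0.14 and PRL, a replication licensing factor, by 0.64 ± 0.15. Of 4 flowering time genes, AGL24 fell by 0.66 ± 0.23; it was not past the test without a filter (adjusted p = 0.0913) or without wild type array 1 or 3 or RNAi array 2 or 3 (0.107, 0.101, 0.122 and 0.0929). The flowering list did not pass camera (adjusted p = 0.548). None of 4 heat shock genes passed (median 0.01, or −0.03 with 1 gene at its bound; list adjusted p = 0.883), with ATHSP22.0 at −0.38 ± 0.30 and AT5G48570 at background in all 3 wild type arrays. The values of PHV for vascular development (0.16 ± 0.25), EIF4A-2 for translation initiation (−0.12 ± 0.12) and BGLU28 for sulfur starvation (−0.29 ± 0.35) were not past the test.

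Among cell type markers, PYK10, a beta-glucosidase abundant in roots, rose by 1.92 ± 0.13, from 129 ± 9.20 to 507 ± 63.8. The other 2 root markers, EXPA7 (−0.59 ± 0.29) and EXPA18 (0.14 ± 0.59), were not past the test, and the root list did not pass camera (adjusted p = 0.548). The guard cell gene FMA read −0.40 ± 0.19 and the trichome gene TRY −0.92 ± 0.39 (above background in 2 of 3 RNAi arrays), both not past the test over all probe sets, although TRY passed over the list alone and without wild type array 3 (limma adjusted p = 0.0440). Flower and seed markers are unnamed here. None of the 4 measured reference genes passed the test: they ranged from −0.26 for GAPC2, which read 0.20 after quantile normalization and 0.29 after cyclic loess (limma adjusted p = 0.0208), to 0.34 for AT2G28390, and the list did not pass (adjusted p = 0.887).

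Control probe sets were compared between the groups as well. The 18 probe sets for hybridisation spikes, which are added in equal amount to each sample, averaged 8.89 ± 0.32 (log2 signal, SD, n = 3) in wild type and 8.27 ± 0.19 in RNAi arrays, a difference of −0.62 with an exact permutation p of 0.1, the smallest that 3 against 3 can give. The 25S rRNA probe set varied from 177 to 1619 over the arrays, and its difference of −1.32 had an exact p of 0.2. The 6 actin controls read −0.07 with an exact p of 0.6. Of 6 ratios of 3' to 5' signal, which follow RNA degradation, 3 reached the smallest exact p of 0.1 (adjusted 0.2): the ratio for GAPDH was 0.14 lower and the r2 versions for actin and GAPDH were 0.28 and 0.17 higher in RNAi arrays on the log2 scale.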

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

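The tests in this part on scaling, brightness, poly(A) tails, array labels and dim probe sets were chosen after the results they bear on had been seen; the counts over other splits were planned. Of the control probe sets left out of the limma tests, 2 kinds read higher in every RNAi array than in any wild type array. The 5 GAPDH controls were higher by 0.32 on the log2 scale and the 5 ubiquitin controls by 0.44 (two-sided exact permutation p = 0.1 each, the smallest possible), and both stayed higher under quantile normalization, median centring and cyclic loess, while the 6 actin controls read −0.07 (exact p = 0.6). With 3 arrays in a group, single arrays were not tested as outliers.

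The pattern of 5584 changed probe sets was set against the other splits of the arrays. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Of these, 1 split, the real one, gave as many, and the highest of the others gave 0. Every other split mixes the groups, so a difference between them widens the spread within each side and lowers the calls. The 0 thus says nothing on chance. For the fixed lists the real split gave 4 calls and the highest of the others 1 (1 of 10 splits with as many). The photosynthesis list was called in 2 of the other 9, and the flavonoid, salicylic acid and cold lists in 0. For the families the real split gave 7 against 5 (1 of 10). Here the plastid-encoded genes were called in 6 of the other 9, their ribosomal genes in 5 and their NDH and photosystem genes in 4 each. The UDP-glycosyltransferases were called in 2, and the WRKY and bZIP families in 1 each. The mixed splits still hold part of the group difference, so these counts are not rates of false calls. Unequal scaling as the whole cause is argued against by the 87.9% of calls made in the same direction after quantile normalization. The labelled Col-3 background and the phosphinothricin, shared by all 3 RNAi arrays, remain open beside the RNAi itself and were not tested. A difference in array handling between the groups remains open too. The hybridisation spikes read lower in every RNAi array than in any wild type array. Their difference was −0.52 after quantile normalization, −0.67 after median centring and −0.45 after cyclic loess.

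Photosynthesis genes (median −0.67) and plastid-encoded genes (median −0.69) read lower in the RNAi line. For the photosynthesis list, other probe sets of like brightness had a median of −0.56 (central 95% of 10000 random medians −0.75 to −0.19), so its fall is consistent with lower readings of bright probe sets in the RNAi arrays in general, although those probe sets may hold photosynthesis genes unnamed here. For the plastid-encoded genes the same comparison gave −0.31 (−0.46 to −0.16). For their 9 NDH genes (median −0.95) it gave −0.27 (−0.65 to 0.24) and for their 15 ribosomal genes (median −0.83) −0.24 (−0.55 to 0.20). These medians lay below their ranges, which argues against brightness as the whole cause, though only weakly. The draws take each gene's match independently, while plastid-encoded genes can vary together, so the ranges may be too narrow. For their 20 photosystem genes (median −0.56) the comparison gave −0.38 (−0.62 to −0.10), and brightness could account for the fall of these. A lower yield of RNA without poly(A) tails would lower mitochondria-encoded genes too. Their median was 0.23 (quartiles −0.10 and 0.61, against −0.95 and −0.50 for the plastid), so those measured did not fall as a group. They were far dimmer, however, with a mean log2 level of 5.57 against 9.58 for the plastid. They thus cannot show whether bright transcripts without tails were lost. The 25S rRNA reading, lower by 1.32 but with an exact p of 0.2, does not decide either, and a lower yield remains open. A lower level of plastid transcripts in the RNAi line remains a hypothesis, and so does variation between arrays, since the mean log2 level of the plastid-encoded genes ranged from 8.64 to 9.54 over the RNAi arrays against 9.90 to 10.1 in wild type.

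OBE1 read 19.9 in RNAi array 1, within the wild type range, and 2.33 and 5.38 in the other RNAi arrays. A mislabelled wild type array is argued against, since RNAi array 1 correlated at 0.968 or more with the other RNAi arrays and at most at 0.917 with wild type arrays. The spread of dim probe sets cannot be told apart from a weaker knockdown in that sample: of 500 probe sets of like brightness, 8.0% had as wide a range over the RNAi arrays with the offset (1.57 log2 units for OBE1) and 3.8% without it (3.09). A construct whose own transcript the probe set detects is a further possibility that was not tested.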

How the results depend on the processing

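Cyclic loess, the families and the family without CYP71 were chosen after the data were seen. The other alternatives were planned, and all of them were run. The count of 5584 changed probe sets ranged from 4395 to 5491 when 1 array was left out and from 4810 to 6778 under the other alternatives, apart from 2713 with 1 probe set for each gene, where fewer probe sets were tested. The share of rises among the calls was 52.9%, and 45.4% with median centring, 47.4% with quantile normalization and 54.9% with cyclic loess. No probe set called in the reported fit was called in the opposite direction under any of these. Of 54 named genes past the test, 49 passed in the same direction under every alternative run for them, and 5 did not pass under at least 1: AGO7, AGL24, EXPA15, LHCB4.1 and, with cyclic loess, PSAE-1 (−0.32, adjusted p = 0.0800).

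OBE1 ranged from −1.61 to −0.82 with 1 array left out and was −1.22 with median centring and −0.59 with the offset at the 40th percentile; its limma adjusted p ranged from 0.0213 to 0.216 over its alternatives, and it fell under the filter with the offset at the lowest percentile and with the stricter filter. Some genes not past the reported test changed sign: PHV (−0.089 to 0.29 with 1 array left out), GAPC2 (0.20 with quantile normalization, 0.29 with cyclic loess, then past the test) and EIF4A-2 (0.060 with cyclic loess).

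Among lists, adjusted p rose past the threshold for photosynthesis (0.313) and cold, drought and abscisic acid (0.104) with quantile normalization, and likewise with cyclic loess (0.502 and 0.129). With an estimated correlation all 4 calls were lost, at 0.325 for salicylic acid and immunity, 0.553 for photosynthesis, and 0.284 for cold and for flavonoids. No list or family passed in that setting, where 0.284 was the lowest for a list and 0.405 for a family. The loss thus does not set these lists apart from others. With fry, which asks whether a list's genes move on balance one way, auxin response and root markers (0.0278 each), jasmonate (0.0324) and cell wall loosening (0.0387) passed as well. Lists not past the test changed direction: auxin response without a filter (0.919) and with the brighter 50% (0.574), heat shock (0.626 to 0.919 with 1 array left out) and reference genes (0.772 to 0.964). The filter changed the members tested for auxin response, to 12 and 4 from 7. The heat shock and reference lists had small medians where they turned, −0.017 and 0.0012. Whether anything else moved these lists was not tested. With the brighter 50%, 6 of 11 lists kept enough members to be tested.

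Replicate numbers are shared between the groups but did not pair the arrays: deviations of same-numbered arrays correlated at −0.0338, −0.0319 and −0.0318, and no wild type array matched its own number best. With the replicate block the count was 5253, and no named gene or fixed list changed its call. Dim signals limit what can be seen, since 21.3% to 33.8% of probe sets on an array lay at or below background.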

Other observations

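The families and genes in this part were chosen after the data were opened, and the single genes after their values were seen. Of 67 measured plastid-encoded genes 47 fell and 0 rose in the RNAi line (camera adjusted p = 9.09e-09; adjusted p = 0.405 with an estimated correlation), and at the deposited scaling all 67 read below 0, from −1.81 to −0.02. Among them were 13 of 15 ribosomal protein genes (median −0.83), 8 of 9 genes of the NDH complex (median −0.95) and 14 of 20 photosystem genes (median −0.56); the calls of the latter 2 groups were lost after quantile normalization (adjusted p = 0.179 each) and cyclic loess (0.185 each), and that of the NDH genes with fry (0.0724). After quantile normalization the median of the photosystem genes shrank to −0.36 (quartiles −0.72 and −0.093, before it −0.98 and −0.48). That of the NDH genes did not shrink, at −1.03, but their quartiles spread to −1.32 and −0.16 from −1.26 and −0.53, as the smaller falls shrank, and 5 of 9 were past the test. Cyclic loess gave medians of −0.272 and −1.003. With an estimated correlation all 3 of these groups lost theirs (0.405 each, the lowest value of any family in that setting). The photosystem II gene psbA (−1.69 ± 0.53, log2 ± SE, 3 arrays each) and petG of the cytochrome b6f complex (−1.81 ± 0.32) fell. Of 9 measured mitochondria-encoded genes 1 rose and 0 fell.

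Of 5 measured WRKY transcription factor genes 4 rose (median 2.07; camera adjusted p = 0.00103, or 0.405 with an estimated correlation): WRKY6, WRKY47 (2.17 ± 0.18), WRKY53 and WRKY22 (1.61 ± 0.25, above background in 1 of 3 wild type arrays). Of 9 bZIP genes 3 rose, among them BZIP60 (1.25 ± 0.21) and BZIP28 (1.68 ± 0.16), which act in the unfolded protein response (adjusted p = 0.0265, lost without a filter at 0.116, where the median was 0.080, and with an estimated correlation at 0.405). Of 26 UDP-glycosyltransferase genes 10 rose and 2 fell (adjusted p = 0.0466), among them UGT72E1 (2.59 ± 0.13) and UGT76B1, at least 3.69-fold higher since all 3 wild type arrays lay at background. That call depended on the processing: it was lost with the lowest offset (0.0643), the brighter 50% (0.0549), quantile normalization (0.0540), cyclic loess (0.0677), camera on ranks (0.0671) and an estimated correlation (0.405), and without wild type array 1 or 3 or RNAi array 2 (0.0802, 0.0557 and 0.0789). Its median was 0.14, and again 0.14 after quantile normalization and 0.20 after cyclic loess; after the former its unadjusted p was 0.00973 against 0.0117, so the call ended through the adjustment over the families. The symbols of cytochrome P450 genes took in 1 cyclophilin gene, CYP71, which did not pass. With it 8 of 15 rose and the family did not pass (adjusted p = 0.0507), although 8 alternatives gave 0.0146 to 0.0484, and an estimated correlation gave 0.405. Without it, a choice made after that test, the adjusted p over 14 genes was 0.0435. Expansins, with 2 risen and 5 fallen of 13 (0.0541), tubulins, with 4 of 7 fallen (0.0541), and SWEET sugar transporters, with 4 of 12 fallen (0.111), did not pass. With fry these 3 passed (0.0166, 0.0292 and 0.0417), as did expansins without wild type array 2 (0.0445) and tubulins under 4 other alternatives (0.0391 to 0.0415). EXPB1 fell by 1.76 ± 0.16 and SWEET4 by 1.35 ± 0.26.

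CC-type glutaredoxins moved both ways. Of 21 loci of this class, 15 were measured, of which 8 fell, 3 rose and 4 did not pass. Those that fell included AT4G15660 (−1.74 ± 0.27), AT4G15700 (−1.50 ± 0.36) and AT1G03020 (−1.35 ± 0.35) besides those named above, the last 2 of these above background in 2 of 3 RNAi arrays, and AT5G11930 (1.92 ± 0.20), AT4G33040 (1.72 ± 0.22) and GRX480 rose. SPCH and STOMAGEN, genes of stomatal development, fell by 1.69 ± 0.30 and 1.32 ± 0.13, while the guard cell gene FMA (−0.40 ± 0.19) was not past the test. The cytokinin response regulator ARR15 fell by 1.90 ± 0.35 and the chlorophyll synthesis gene CHLI2 by 1.22 ± 0.13. SPCH lay above background in 1 of 3 RNAi arrays and ARR15 in 2 of 3.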
